A study of Drosophila melanogaster with 2 samples.

How the data were processed

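Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out by the authors with an antibody against GFP on whole Drosophila melanogaster embryos of mixed sex, 0 to 24 h old, from a transgenic line that carries NC2beta fused to eGFP. Per the labels' protocols, chromatin was sheared by sonication to fragments of 200 to 800 bp. The samples form 1 group with 2 biological replicates, numbered 1 and 3 in the labels, so the design allows no test between groups.

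The deposited lists give each region's interval, a peak height, a q value and a summit offset. Each replicate has a list of 30000 regions that includes background, called per sample, and a list of 30000 regions was also made from the pooled replicates. Per the file lists deposited with them, these lists derive from the alignments and a further file, taken to be the control alignment because the control-normalized signal derives from it too, and not analysed here. The authors' set of optimal peaks, chosen for irreproducible discovery rate (IDR), holds 3897 peaks in build dm6, and these were exactly the 3897 highest regions of the pooled list. The height of a region is the authors' signal value for that peak, in a unit not given in the sources used here, and was used only to describe, rank or filter regions within a list. The second measure is the −log10 of the q value in the deposited lists. It sat at its ceiling of 4.08 for all optimal peaks and was not used to rank them. The aligner and the peak caller are not given in the sources used here. The read totals behind the lists are unknown, so no depth-based interval is given.

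The dm6 lists were set against the Release 6 genome and the Ensembl release 115 gene annotation, after a check that every region lay within its chromosome on arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists were used only where no annotation was needed, and no coordinate was converted. Coordinates are 1-based dm6 positions. The annotation held 19253 unique transcription start sites (TSSs) of 13945 protein-coding genes on these arms. A TSS was called bound when the summit of an optimal peak lay within 250 bp, and a gene when any of its TSSs was. Bound therefore means only that such a peak was present.

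Shares at TSSs, RNA genes and shared regions were compared with 100 seeded placements of the summits at random positions on the same chromosome (permutation, one-sided), for which the smallest possible p is 0.0099. Random placement includes sequence in which no region can be called. Core promoter elements were sought at unique TSSs, with position 1 at the TSS. They were compared by two-sided Fisher's exact tests between bound and unbound TSSs, and between the top and bottom tertiles of bound TSSs by peak height, with Benjamini-Hochberg adjustment over 11 elements. TATA started between −40 and −20 and the initiator A lay between −10 and 10, each with at most 1 mismatch. The downstream promoter element (DPE) had to start at 28 counted from that A. As a control for base composition the window was moved 200 bp downstream, or for the DPE to 11 spacings from 38 to 48. The share of 24 gene lists with a bound TSS was compared with all other protein-coding genes by the same test, adjusted over the lists. The lists were ribosomal proteins, mitochondrial ribosomal proteins, proteasome, oxidative phosphorylation, translation factors, splicing, RNA polymerase II and general factors, cell cycle and replication, Hox cluster, segmentation, dorsoventral, E(spl) and proneural, early zygotic, muscle, neuronal, cuticle, heat shock, histone, chemoreceptor, testis, ovary and eggshell, phototransduction, accessory gland and immune peptides. Motifs within 100 bp of a summit were compared with a 200 bp window centred 500 bp to the side of the same peak by exact McNemar tests, adjusted over 7 motifs. Genes, TSSs and peaks are not independent replicates, and their p-values describe these lists, not the spread between embryos. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only.

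For each optimal peak the nearest region within 250 bp in each replicate gave that replicate's height, divided by its median over the optimal peaks. These relative heights are given as mean ± SD with n = 2. The genes named were fixed by rule before the data were examined: the genes of the 20 highest peaks with a TSS within 250 bp and a region among the highest 3897 within 250 bp in both replicates, up to 3 bound members of highest signal per list, every unbound member where at most 3 were unbound, NC2beta, NC2alpha and Tbp, the 3 highest peaks farther than 1000 bp from a protein-coding TSS, and the 3 genes with the largest difference between replicates in each direction. The tests, lists and most alternatives were also fixed then. These alternatives were each replicate alone, the highest peaks, other distances, mismatches, TSSs, backgrounds, windows and overlaps, and the dm3 lists.

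The code was tested on simulated data, where all 16 checks passed in their final form. In an earlier form, checks on elements and gene lists asked for no call beyond the simulated ones, and a chance call failed them. They were replaced by recovery of every simulated effect together with measured false calls. Among sets with no effect, 4.25% of 400 shuffles of bound labels gave any element call. The simulated sequences were independent, whereas neighbouring TSSs in the genome can share sequence and a peak. The rate therefore does not measure false calls in these data. Python 3.11.15, numpy, pandas, scipy and matplotlib were used. The individual ribosomal protein genes without a bound TSS are not reported here.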

Results

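The binding of NC2beta was mapped by anti-GFP ChIP-seq in whole embryos that carry the protein fused to eGFP. NC2beta is a subunit of the NC2 (Dr1 and DRAP1) cofactor, which binds the TATA-binding protein and is known to act on core promoters in opposite ways according to their elements. The samples were 2 biological replicates, and the authors' optimal set held 3897 peaks with heights from 74.1 to 1496 and a median of 112. Read totals were not known. Arm 3R held 947 peaks, 3L 818, 2L 731, 2R 713, X 663 and chromosome 4 held 25. Density ranged from 28.2 peaks per Mb on X to 31.1 on 2L, and was 18.5 on chromosome 4.

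The first question was whether the replicates marked the same places. Of the 3897 highest regions of replicate 1, 2949 (75.7%, 95% exact interval 74.3 to 77.0) had a summit within 250 bp of one of the 3897 highest of replicate 3. Random placement gave 1.48% on average (permutation p = 0.0099, the smallest possible). Across the 3884 optimal peaks with a region in both, Spearman's rho of the heights was 0.68; this is across peaks, which are not independent replicates. Among genes with a bound TSS, the transcription factor gene aop (relative height 0.315 in replicate 1 and 1.31 in replicate 3), Rad23 (0.318 and 1.08) and CG42676 (0.246 and 0.837) were the most different toward replicate 3. In the other direction were noc (1.15 in replicate 1 and 0.241 in replicate 3), Tapdelta (1.10 and 0.233) and CG14715 (1.07 and 0.240). Their replicate 3 heights were 11.12 (noc), 10.75 (Tapdelta) and 11.08 (CG14715), below the median of 14.72 for that replicate's list. The replicate 1 height of CG42676 (16.96) was below its list's median of 18.6, while aop (21.65) and Rad23 (21.86) were above it. The nearest region was taken, not the highest, so a higher region nearby may have been missed, which was not checked. These values may therefore not be differences in binding. Of these 3884 peaks, 93.9% had relative heights within 1 log2 unit between replicates. The optimal peaks were chosen for reproducibility and are the highest pooled regions, so part of the likeness of their heights is built in.

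Promoters held the largest class of peaks. Of the 3897 summits, 1956 (50.2%, 95% exact interval 48.6 to 51.8) lay within 250 bp of a protein-coding TSS, against 6.28% on average for random placement (permutation p = 0.0099, the smallest possible). Introns held 1206 summits (30.9%, random 41.3%), intergenic sequence 563 (14.4%, random 29.2%), coding sequence 11 (0.282%, random 15.6%) and 3′ UTRs 30 (0.770%, random 4.80%). The classes share out all summits, so the excess at promoters lowers what is left for the others. An intron or intergenic share below random therefore does not show that peaks outside promoters avoid such sequence. The control alignment was not analysed here, so DNA recovered at open promoters whatever the tagged protein was not measured, for this share or for the gene lists and elements. Of the 26103 pooled regions below the optimal set, 21.1% lay at a TSS. Summits at promoters lay upstream of the TSS more often than downstream, with a median of −51 bp (quartiles −108 and −1). A gene with a bound TSS was found for 2450 of 13945 protein-coding genes (17.6%).

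**Figure D1:**
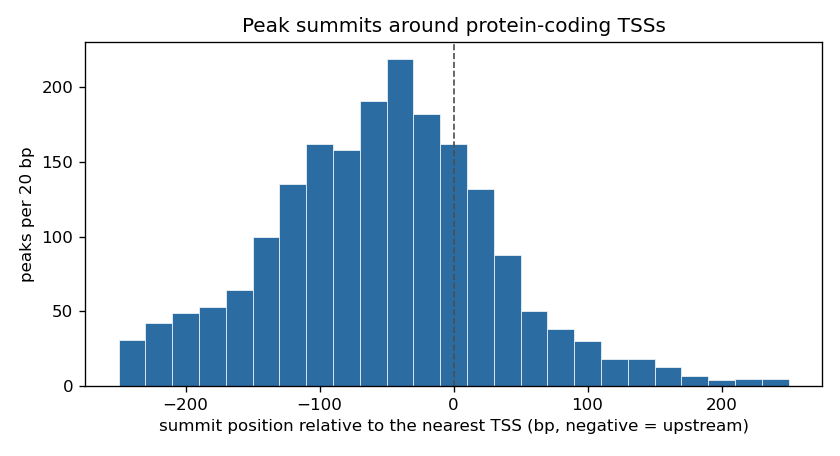
Number of optimal peaks per 20 bp (y axis) by summit position relative to the nearest protein-coding TSS in bp (x axis, negative upstream), for the 1956 peaks within 250 bp of a TSS. The median is −51 bp.

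The highest promoter peak lay at px (FBgn0003175), on 2R from 22514093 to 22514498, with a height of 1460 and a relative height of 12.8 ± 0.248 (SD, n = 2). The peak at RpL7 (FBgn0005593), which encodes a protein of the large ribosomal subunit, covered 2L from 10200816 to 10201242, with its summit 29 bp downstream of the TSS and a relative height of 12.1 ± 0.789 (SD, n = 2). The sequence from 40 bp before the RpL23A (FBgn0026372) TSS at 1668654 on 3L (minus strand) is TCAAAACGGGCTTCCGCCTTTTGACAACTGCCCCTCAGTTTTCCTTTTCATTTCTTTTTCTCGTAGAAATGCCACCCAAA, and it holds a TCT element, the polypyrimidine initiator of ribosomal protein genes. The RpL23A peak had a relative height of 11.2 ± 0.327 (SD, n = 2). CG14100 stood just above it (11.7 ± 0.367). Below it were Ugalt (10.6 ± 0.698), CG1888 (9.65 ± 0.254), Chro (9.59 ± 0.841), which encodes a chromatin protein of interbands, Art3 (8.88 ± 0.915), RpL14 (8.61 ± 2.01) and PNPase (8.57 ± 0.994). The remaining genes of the 20 highest such peaks were RpS27, RpLP0, CenG1A, Tcs5, CG18549, mRpL41, RpL13A, CG9147, RpL41 and Pal1, with mean relative heights from 5.97 at Pal1 to 8.06 at RpS27. NC2alpha, which encodes the partner subunit, had a bound TSS (height 267, relative height 2.34 ± 0.0208, SD, n = 2), and NC2beta and Tbp had none.

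Ribosomal protein genes stood apart from all other lists. Of 86 such genes, 76 (88.4%) had a bound TSS, against 17.1% of other protein-coding genes (Fisher's exact test, adjusted p = 2.0e-45), and the median height of their peaks was 319. Also more often bound were splicing genes (12 of 26, adjusted p = 0.0021 by the exact test), translation factors (22 of 52, adjusted p = 0.00013 by the exact test) and mitochondrial ribosomal protein genes (24 of 73, adjusted p = 0.0044 by the exact test). The highest splicing members were SF2 (height 146), Prp31 (133) and Sf3b1 (126), the highest translation factors eEF1gamma (613), eIF6 (484) and eEF5 (444), and the highest mitochondrial members mRpS10 (1002), mRpL41 (773) and mRpL23 (454). The peak at mRpS10 is the same as that at its neighbour Art3. When only genes with a pooled region of any height at a TSS were compared, a choice made after seeing the data, ribosomal protein genes alone kept the call. Mitochondrial ribosomal protein genes also did not pass within 100 bp (13.7%, adjusted p = 0.45, exact test), nor translation factors among genes with 1 annotated TSS (18.8%). For the 50% of peaks that were highest, the splicing, translation factor and mitochondrial lists still passed. The shares were 26.9% for splicing (exact test, adjusted p = 0.023) and 21.2% for translation factors (exact test, adjusted p = 0.023). Mitochondrial members had 17.8% (exact test, adjusted p = 0.046). Splicing also passed within 100 bp, at 26.9%. Fewer peaks bind fewer genes of every kind, so a lower share alone does not show weaker enrichment.

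Genes of the cuticle, testis, accessory gland, chemoreceptor and immune peptide lists were less often bound. No TSS was bound among 122 cuticle genes, 50 testis genes, 49 accessory gland genes and 32 immune peptide genes, and 1 was bound among 230 genes of the chemoreceptor list, namely Obp99b (exact tests, adjusted p from 3.6e-17 for chemoreceptors to 0.0093 for immune peptides). That list took Obp genes by symbol along with receptor genes, and Obp99b is one of the former. Its summit lay 244 bp upstream of the TSS, and no gene of the list was bound within 100 bp. Histone genes (0 of 111, adjusted p = 4.0e-09 by the exact test) lie in a tandem array of near-identical copies, and no histone gene had a pooled region of any height within 250 bp, so their value is uncertain. Muscle (0 of 21, but 4.76% in each replicate alone) and phototransduction genes (0 of 16, but 6.25% in replicate 3 alone) did not pass the adjusted test. None of these lists passed it when only genes with a pooled region at a TSS were compared, where chemoreceptors had 1 of 18 and cuticle genes 0 of 6. Immune peptides also did not pass for the 50% of peaks that were highest, within 100 bp or among genes with 1 annotated TSS.

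The other lists did not pass it with all peaks and both replicates within 250 bp. Bound members numbered 10 of 32 for the proteasome (Rpn3, Rpn5 and Rpn6 highest), 22 of 84 for oxidative phosphorylation (COX5A, ND-MWFE and ND-ASHI), 14 of 44 for RNA polymerase II and general factors (Polr2H, NC2alpha and Polr2F), 11 of 34 for cell cycle and replication (stg, dpa and aurA) and 8 of 25 for heat shock (Hsp83, Hsp27 and Hsp26). Cell cycle and replication genes passed in replicate 3 alone (41.2%) and replicate 1 alone (38.2%), for the 50% of peaks that were highest and within 100 bp (23.5% in both). RNA polymerase II and general factors passed in replicate 1 alone (34.1%) and within 100 bp (27.3%), oxidative phosphorylation within 100 bp (19.0%) and heat shock for the highest peaks (28%). For genes of embryonic patterning they numbered 6 of 30 in segmentation (Kr, wg and opa), 5 of 28 in dorsoventral (cact, rho and vnd), 4 of 21 in E(spl) and proneural (Tom, E(spl)malpha-BFM and E(spl)mbeta-HLH), 1 of 11 in the Hox cluster (bcd) and 1 of 14 in early zygotic genes (Sxl). The Sxl summit lay by the most upstream annotated TSS of the gene, so it does not show binding at other start sites of Sxl. Neuronal genes had 2 of 18 (Csp and Syx1A). The 1 bound member of 23 in the ovary and eggshell list was Cp190, which encodes an insulator protein and entered the list by its symbol.

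**Figure D2:**
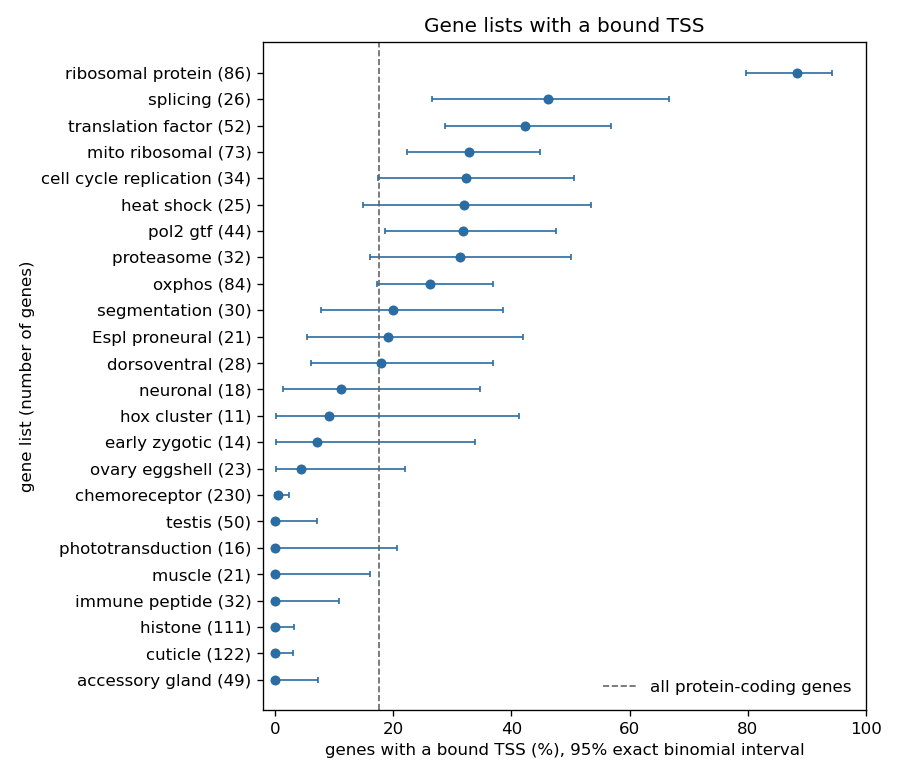
Share of each gene list with a bound TSS in % (x axis) with its 95% exact binomial interval; the number of genes is beside each name (y axis) and the dashed line is the share of all protein-coding genes. Ribosomal protein genes lie at 88.4%, against 17.6% of all protein-coding genes.

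The core promoters of bound TSSs held fewer TATA boxes and more of Motif 1, Motif 6, Motif 7 and DRE. TATA was found at 6.63% of 2867 bound and 14.2% of 16386 unbound TSSs (odds ratio 0.43, or 0.28 with strict mismatches, adjusted p = 1.9e-32, Fisher's exact test), and the initiator at 43.0% and 50.7% (odds ratio 0.73, adjusted p = 5.4e-14, exact test). The DPE was found at 2.72% and 2.87%, with an odds ratio of 0.94 (95% interval 0.74 to 1.20, adjusted p = 0.72, exact test). Motif 7 (16.9% against 5.49%, odds ratio 3.49), Motif 1 (26.6% against 13.5%, 2.33), the DNA replication-related element DRE (21.0% against 10.7%, 2.22) and Motif 6 (13.0% against 8.57%, 1.60) were more common at bound TSSs, with adjusted p from 4.9e-83 to 4.4e-13 (exact tests). At the shifted position the odds ratio was 1.64 for Motif 7, 1.31 for Motif 6, 1.19 for Motif 1 and 1.13 for DRE, and 0.84 for TATA. TCT was also more common (3.07% against 0.879%, odds ratio 3.57, adjusted p = 9.3e-18, exact test), but its odds ratio was 6.003 for the highest peaks, 5.36 within 100 bp and 0.94 without ribosomal protein genes. The motif of the early activator Zelda was less common (0.767% against 1.27%, adjusted p = 0.027, exact test), while GAGA repeats (5.20% against 5.98%) and E-boxes (65.5% against 65.9%) did not pass the test. The Zelda difference did not pass in replicate 1 alone, within 100 bp, with 1 TSS per gene or without ribosomal protein genes, whereas GAGA was less common for the 50% of peaks that were highest and within 100 bp, and DPE with strict mismatches (0.65). A further comparison, chosen after seeing the data, used only those unbound TSSs that had a lower pooled region. Against these the odds ratio was 0.78 for TATA, 1.84 for Motif 7, 1.24 for Motif 1 and 1.15 for DRE. Motif 6 did not pass (1.09, adjusted p = 0.29, exact test), and GAGA was less common (0.66, adjusted p = 6.0e-05, exact test). At the shifted position the odds ratios against these TSSs were 1.236 for Motif 1, 1.495 for Motif 7 and 1.35 for Motif 6. They were 0.93 for DRE, 0.957 for TATA and 0.81 for GAGA. The value for Motif 1 was thus nearly the same at both positions (1.243 and 1.236). For Motif 1 this comparison therefore shows no excess beyond base composition.

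**Figure D3:**
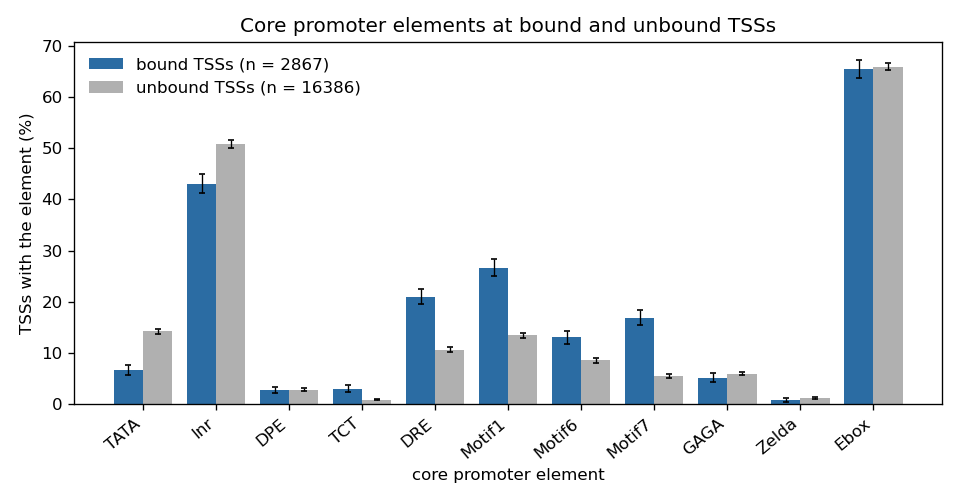
Share of TSSs with each core promoter element in % (y axis) for bound and unbound TSSs, with 95% exact binomial intervals. TATA is at 6.63% of bound and 14.2% of unbound TSSs.

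Among bound TSSs, TCT was most frequent at the highest peaks. It was found at 7.33% of the top tertile of 955 TSSs and 0.733% of the bottom tertile (odds ratio 10.7, or 5.48 within 500 bp, adjusted p = 1.3e-13, Fisher's exact test). The initiator was more common in the top tertile (47.1% against 40.1%) and Motif 1 less common (22.9% against 29.2%), each with adjusted p = 0.0085 (exact tests). The initiator did not pass the test in either replicate alone, within 100 bp or within 500 bp, and with strict mismatches its odds ratio turned from 1.33 to 0.82 (adjusted p = 0.33, exact test). Motif 1 did not pass in replicate 1 alone or for the 50% of peaks that were highest. In replicate 1 alone DRE passed instead as less common in the top tertile (odds ratio 0.66). GAGA passed as less common in replicate 3 alone (0.53) and within 100 bp (0.38), and Motif 6 within 500 bp (0.70). TATA was found at 6.70% and 6.91%. Without ribosomal protein genes neither TCT (1.10% against 0.657%) nor the initiator (43.2% against 40.3%) passed the test.

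Promoter and distant summits were each compared with windows to their own side, and the motifs that passed differed. The classes were not tested against each other. Within 100 bp of the 1956 promoter summits, DRE was found in 17.3% against 2.61% to the side, Motif 7 in 13.7% against 2.04%, Motif 1 at 562 summits against 196 windows to the side, and Motif 6 in 10.6% against 3.22% (exact McNemar tests, adjusted p from 2.5e-54 to 2.8e-20). DRE and Motifs 1, 6 and 7 are core promoter elements, and these summits were chosen for a nearby TSS. They can therefore be more common than to the side whatever the tagged protein. At unbound TSSs DRE was at 10.7% against 2.23% 200 bp downstream, and Motif 7 at 5.49% against 2.09%. Motif 1 was there at 13.5% against 6.78%, and Motif 6 at 8.57% against 4.33%. The comparison thus does not tie these motifs to NC2beta. Zelda motifs were less common at promoter summits (0.665% against 1.84%, adjusted p = 0.0020, exact McNemar test). At the 1355 peaks farther than 1000 bp from any protein-coding TSS only Motif 1 passed (11.1% against 7.16%, adjusted p = 0.0037, exact McNemar test), and it did not pass in either replicate alone, for the highest peaks, with a 50 bp window or with the control 1000 bp to the side. The highest peak of all, with a height of 1496, was such a peak, in an intron of ush on 2L from 480866 to 481292, 1403 bp from the nearest protein-coding TSS, that of cbt. The next lay in an intron of CG11050 on 2L from 6612497 to 6612920 (height 1141), and the following one between genes on 2R from 13035151 to 13035500 (height 985), 11917 bp from the TSS of CG13323.

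Genes of small RNAs were bound in part. A summit lay within 250 bp of 7 of 32 snRNA genes (21.9%, 95% exact interval 9.28 to 39.97, random mean 2.06%, permutation p = 0.0099), among them genes of U1, U2, U4, U5 and U6 RNAs. It lay there for 13 of 290 tRNA genes (4.48%, random mean 1.60%, permutation p = 0.0099) and 12 of 269 snoRNA genes (4.46%, random mean 1.79%, permutation p = 0.0495), but the tRNA share did not pass with either replicate alone, for the highest peaks or within 100 bp, nor the snoRNA share within 100 bp. These p-values were not adjusted over the RNA classes, and that of snoRNA genes lay just under the threshold of 0.05. Random placement ignores that many peaks lie at promoters. RNA genes near protein-coding TSSs can therefore have a summit nearby that belongs to those TSSs, and neighbouring RNA genes can share a peak. The values were 5 of 260 for pre-miRNA genes (permutation p = 0.40) and 0 of 99 for rRNA genes, which lie in repeats.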

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

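The tests of peaks far from TSSs, of gene lists and of the NC2beta locus were written before their results were seen, except the tests of the 7-base sequence and of heights at the NC2beta locus, which were chosen only after the result was seen. The authors' dm3 set held 2 optimal peaks on scaffolds outside the main arms, sequence that the comparisons did not use: 1 on the 3LHet scaffold with a height of 150 and 1 on the U scaffold with a height of 93.1. No explanation was tested for them.

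The first pattern is the 1355 peaks farther than 1000 bp from any protein-coding TSS, among them the highest peak of all. TSSs of genes that do not code for protein account for few of them, since 3.69% of these summits lay within 250 bp of such a TSS (95% exact interval 2.75 to 4.84). Annotated transposable elements held 0.148% of the summits, so few of these summits lay in such elements. They held 1.48% of positions 2000 bp to the side (exact McNemar p = 0.00012). That comparison cannot decide more, since positions to the side may lie in repeats where no region can be called. The 7-base sequence CAGTGTA, most enriched on 2L and 2R, was found at 13.2% of 872 far summits on the other arms and at 1.61% of windows to the side, 7.97 times as common (exact McNemar p = 9.2e-22), and its bases in reversed order, read on either strand as ATGTGAC, at 1.49% and 2.06%. CAGTGTA was at 12.5% of all 1355 far summits, so most far summits lack it. The test was chosen after the result was seen, so the other arms are not an independent check. For summits that hold CAGTGTA, a candidate explanation is a sequence-specific factor there. NC2beta may bind directly, through that factor, or be recovered by the antibody, which these data cannot separate. What lies behind the other far peaks stays open.

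The second pattern is the more frequent binding at 4 gene lists, those of ribosomal proteins, mitochondrial ribosomal proteins, translation factors and splicing; among genes with a pooled region only the first passed. The tables argue against more annotated TSSs per gene as its cause, since 3 of the 4 lists kept the call among genes with 1 annotated TSS; translation factors did not. DNA recovered at highly transcribed genes whatever the tagged protein stays open: 4.48% of tRNA genes had a summit within 250 bp, above every random placement, as this explanation needs. That share did not pass with either replicate alone, and 8 of the 13 tRNA genes lay within 1000 bp of a protein-coding TSS. DNA recovered at open promoters whatever the tagged protein stays open too, for these lists and for the share of peaks at TSSs, since the control alignment was not analysed here, as does recruitment of NC2, since no biological explanation was tested.

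The last pattern concerns the locus of the tagged gene. The pooled list held 8 regions within 10000 bp of NC2beta, and the median of other protein-coding genes was 8; replicate 1 had 9 and replicate 3 had 5. The median height of the pooled regions there was 32.4, above 64.4% of 12390 other genes with such a region, and the highest, at 231.5, was above 83.1%. These values argue against an extra copy of the locus raising the number or the median height of regions in these lists beyond most other genes, and a smaller rise stays open. They cannot decide whether an extra copy is present, since a control from the same line would carry it too and could offset it. The control alignment was not analysed here.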

How the results depend on the processing

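The comparisons with random regions of the pooled list, with unbound TSSs that have a lower region, with genes that have a pooled region and without ribosomal protein genes were chosen after seeing the data. Under every alternative run, the share of peaks at TSSs stayed above its comparison (47.5% to 51.6% with 1 replicate alone), shared regions stayed above random placement (52.6% to 77.8%), and the counts of core promoter elements more and less common at bound TSSs and of motifs at promoter summits stayed within 1.5 times. Of 88 alternative values for these leading results 69 were unchanged in that sense and 19 moved. The cause was not tested for those below unless stated. With a single replicate, elements more common at high peaks numbered 1 in both cases, those less common 1 to 2, and motifs more common at far peaks 0 in both cases. Elements more common at high peaks numbered 1 within 100 bp, 1 within 500 bp, 1 with strict mismatches and 0 without ribosomal protein genes, where bound TSSs with TCT fell from 88 to 22; those less common numbered 2 within 100 bp, 2 within 500 bp and 0 for the 50% of peaks that were highest. Lists more often bound numbered 1 and less often bound 0 among genes with a pooled region, where most genes of the tissue lists drop out. Motifs more common at far peaks numbered 0 for the highest peaks, 0 with a 50 bp window and 0 with the control 1000 bp to the side, and 1 was less common for the highest peaks. RNA classes numbered 1 within 100 bp.

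Of 462 alternative values of single elements, lists, motifs and RNA classes, 356 kept direction and side of the threshold and 53 turned direction, the others crossing the threshold. Turned values are odds ratios for elements, ratios for motifs at summits and percentages bound for lists. The direction of a list is relative to the share of other genes, which changes with the setting. A list can therefore turn with its own percentage unchanged, as Hox did for the highest peaks (9.09%) and segmentation within 500 bp (20%). TCT at bound TSSs was 0.94 without ribosomal protein genes. With 1 replicate alone the ranges were E-box at bound TSSs 1.02 to 1.03, and by height TATA 0.98 to 1.06, Motif 6 0.95 to 1.01 and Zelda 0.57 to 1.00. For lists they were Hox 9.09% to 18.2%, segmentation 3.33% to 13.3%, dorsoventral 10.7% to 21.4% and E(spl) 14.3% to 23.8%, and for motifs E-box at promoters 0.99 to 1.01, far DRE 0.61 to 1.28 and far Motif 7 0.76 to 1.13. For the highest peaks E-box at bound TSSs was 1.06, by height TATA 1.08, Motif 6 1.14, Motif 7 0.90, GAGA 1.28 and E-box 0.86, lists Hox 9.09%, segmentation 0%, dorsoventral 3.57% and E(spl) 0%, far DRE 0.93 and pre-miRNA 0.769%. Within 100 bp E-box at bound TSSs was 1.00, by height DPE 0.49, DRE 1.12 and Motif 7 0.79, segmentation 10%, neuronal 11.1% and pre-miRNA 0.385%. Within 500 bp GAGA was 1.08 at bound TSSs and 1.07 by height, segmentation 20% and neuronal 22.2%. With strict mismatches TATA by height was 2.13, the initiator 0.82 and DPE 0.58. Among genes with a pooled region the proteasome was 34.5%, RNA polymerase II 35.9%, segmentation 25%, dorsoventral 21.7% and E(spl) 23.5%. Among genes with 1 annotated TSS oxidative phosphorylation was 12%, Hox 20% and neuronal 20%, and with 1 TSS per gene dorsoventral was 14.3%. At summits, GAGA at promoters was 0.67 and far Motif 6 1.29 with a 50 bp window, and far Motif 7 1.18 and far GAGA 1.14 with the control 1000 bp to the side. Read depth is unknown, so what it limits was not measured.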

Other observations

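Summits at bound TSSs of ribosomal protein genes lay closer to the TSS, with a median of −26 bp (quartiles −59.5 and 14), than those of all bound TSSs, with a median of −75 bp (quartiles −140 and −16); the difference was not tested.

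A scan of all 7-base sequences, run after the data were seen, gave different leading sequences at promoter and far summits. At promoters ATCGATA led, at 20.1% of summits and 2.76% of windows to the side (exact McNemar, adjusted p = 6.5e-67 over 8192 sequences), followed by CTATCGA at 15.3% and 1.89%. Promoter sequence can differ from windows to the side whatever the tagged protein, so these sequences are not tied to NC2beta. At far summits CAGTGTA led, at 12.5% and 1.33% (exact McNemar, adjusted p = 3.1e-29). It was found at 3.02% of promoter summits and 1.12% of windows to the side of them. Among far peaks it was at 13.3% of the top tertile by height and 11.1% of the bottom tertile (Fisher's exact test, p = 0.36). The sequences behind the leading ones were partly alike. CACACTG, which on the other strand differs from CAGTGTA only in its last base, was at 11.1% of promoter summits and 2.61% of windows to the side. TTAAAAA was more common at both kinds of summit.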
